A study of Mus musculus with 6 samples.

How the data were processed

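RNA was measured in 6 libraries of mouse small-intestinal stem cells, 3 untreated and 3 exposed to interferon gamma (IFNg). Per the labels' protocols, each library began with 2 ng of total RNA, which was turned into cDNA and amplified for 12 cycles with a SMART-Seq v4 low-input kit, and 10 ng of cDNA then went through a KAPA Hyper preparation with 8 further cycles. This chemistry reads full-length polyadenylated transcripts, does not mark the strand and carries no molecular identifiers, so the reads are not independent molecules. All intervals and floors given here cover counting error only.

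The authors deposited 1 table of scaled counts, a signal per gene in which each library's read counts are divided by 1 size factor, per the name of the file. Cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3, DESeq 1.22.1 and the genome build mm10 are named, without their roles or settings, per the submitters' processing notes. The strand setting of the counting and the gene annotation are not given in the sources used here. The table holds 23127 genes and 4 rows for reads given to no gene. Those 4 rows were kept out of library sizes and tests. Over the libraries, reads with more than 1 alignment took 18.5% to 25.0% of all rows' values, reads outside genes 9.67% to 14.2%, unaligned reads 8.83% to 15.4% and ambiguous reads 0.948% to 1.20%. Because reads with more than 1 alignment sat in a row of their own, values of genes with near-identical copies (guanylate-binding proteins, immunity-related GTPases, Tgtp1 and Tgtp2, H2 genes, alpha-defensins) are uncertain, and so are those of genes that overlap a neighbour on either strand.

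Every value was a whole multiple of its library's smallest step. Dividing by that step gave whole numbers for 100% of 138762 values, within 0.01 of a read. The recovered reads in genes were 28508762 in untreated 5, 40224497 in untreated 1, 30487312 in untreated 9, 35959242 in IFNg 6, 33103808 in IFNg 2 and 35577298 in IFNg 10. A single read was thus worth 0.853 to 1.05 scaled counts, and a count of 0 allowed up to 3 reads, or 2.56 to 3.16 scaled counts, per library.

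Groups were taken from the sample titles and treatment labels. Replicate names are the end numbers of the titles (untreated 5, 1 and 9, IFNg 6, 2 and 10). Titles also carry a tag, GFP1 for libraries 5 and 6 and GFP3 for the other 4, whose meaning the labels do not give. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. Whether the untreated cells stood in medium for the same 1.5 h is not stated apart from the titles. No library matched another within sampling noise, since chi-square per degree of freedom between any 2 libraries was 62.7 to 505.

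Whether neighbouring end numbers within a tag pair the libraries (5 with 6, 1 with 2, 9 with 10) was checked once. Deviations from the group means correlated across genes at 0.302 for 5 and 6, 0.404 for 1 and 2 and 0.252 for 9 and 10. All other such correlations between the groups were below 0. Deviations within a group sum to 0 for each gene, so positive values in the pairs push the others below 0. Those negative values therefore add little. Libraries 1 and 2 also had Xist at 8336 and 6147 scaled counts and Ddx3y at 1.72 and 0.964, while the other 4 had Ddx3y at 4219 to 6346. These genes tie libraries 1 and 2 only, and do not show how 5, 6, 9 and 10 pair. The numbers were therefore taken to pair the libraries, from the data and not from a statement in the labels. A fit with the pair as a block is given for each named gene or list whose call it changed.

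The main test, fixed before the data were examined with the gene lists, the alternatives and the rule for named genes, was limma 3.58.1 in R 4.3.3 on log2(scaled count + 1), with a trended and robust prior, two-sided, over 16095 genes with a mean of at least 10 scaled counts. P-values were adjusted by Benjamini-Hochberg and a gene passed below 0.05. Log2 fold changes are on the log2(scaled count + 1) scale, which understates the change of low genes, and folds are ratios of mean scaled counts. On simulated data of 16095 genes for this comparison, the test recovered 4% of 50 genes changed 2-fold, 52% of 50 changed 4-fold, 90% of 50 changed 8-fold and 90% of 50 changed 16-fold, and called 6 unchanged genes. EdgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

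There were 30 gene lists with 678 symbols, 642 of them in the table, covering the interferon response, cell death, stem cells, differentiation, stress, RNA quality and other cell types. A list with at least 5 tested members was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. It was tested again with the correlation estimated for each list and with fry. The estimated version differed in more than the correlation, since p could rise where the estimate lay below 0.01. A call lost in it is not by itself evidence of correlated genes. No list passed in it, without or with the block. Even the guanylate-binding and immunity-related GTPases, at 1.45e-51 with the preset, reached only 0.0502 in it, and 0.255 with the block. A failure in it therefore does not set a list apart from the others. On simulated data the raised list was called and 0 of 29 unchanged lists were. The simulated genes were drawn independently, whereas the estimated correlation of a real list reached 0.966. The simulation therefore does not show how the preset holds for lists of correlated genes. Members were also tested adjusted over the list alone.

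Genes named were the 10 with the largest upward and the 10 with the largest downward log2 change among those that passed, with a mean of at least 50 scaled counts and no overlap between groups, genes from a set of 20 fixed in advance, and up to 4 members of each list by smallest p. Only 1 gene met the downward part. Genes named outside this rule for their change are marked as chosen after their values were seen. Not marked are Xist and Ddx3y, used for the pairing, and genes given only for a call lost with the block or for overlap or likeness to another gene. Positions are those of a GENCODE annotation of the same build, matched by Ensembl identifier for 16037 of the tested genes. Alternatives were other pseudocounts, low-value filters, scalings, tools, blocks and subsets of libraries. A correction for transcript length and GC content (loess per library, 16037 genes), the fits without libraries 1 and 2 or 9 and 10, and the block with an estimated correlation were added after seeing the data.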

Results

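The study asked how the transcriptome of mouse intestinal stem cells changes when they meet IFNg, a cytokine made by T and natural killer cells that acts through the receptor chains Ifngr1 and Ifngr2 and the kinases Jak1 and Jak2. Cells with high Lgr5-GFP, a reporter of the R-spondin receptor gene that marks crypt base stem cells, were sorted from the small intestine of C57BL/6 mice. The treated cells received 1 ng/ml IFNg for 1.5 h in a medium with EGF, Noggin and R-spondin. There were 3 untreated libraries and 3 IFNg libraries, with 28508762 to 40224497 reads in genes and 19734 to 22371 genes above 0. Values below are scaled counts, given as mean ± SD with n = 3 per group.

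Across the tested genes, Pearson correlations of log2 values were 0.925 to 0.971 between libraries of the same group and 0.916 to 0.957 between groups. The first principal component held 35.2% of the variance and separated the title tags: untreated 5 and IFNg 6, tagged GFP1, lay at -54.9 and -88.3, and the 4 libraries tagged GFP3 lay at 18.3 to 59.0. The second component held 28.8% and separated the treatments, with untreated 5, 1 and 9 at -41.5, -44.5 and -41.4 and IFNg 6, 2 and 10 at 0.604, 45.9 and 80.9.

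After 1.5 h of IFNg, 15 of 19 tested guanylate-binding and immunity-related GTPases of cell-autonomous defence rose in limma. So did 5 of 18 interferon regulatory transcription factors. These rises ran from 4.48-fold for Irf9 to 259-fold for Iigp1. The other 4 and 13 did not pass in limma, and 16 of the GTPases passed in DESeq2. Irgm1 (mm10 chromosome 11, 48861968 to 48871683, minus strand), an immunity-related GTPase that acts on intracellular pathogens and autophagy, went from 1013.6 ± 108.5 to 101580 ± 6713 scaled counts, a 100-fold increase. Irf1 (chromosome 11, 53770014 to 53778374, plus strand), the transcription factor that carries much of the secondary IFNg response, rose 33.6-fold from 1773.5 ± 89.3 to 59642 ± 6397, and Cxcl10, a chemokine that attracts T cells, rose 84.6-fold from 325 ± 175 to 27516 ± 2782. The transcriptional repressor Bcl6 fell from 2766 ± 571 to 222 ± 37.3, a 12.5-fold decrease. In the stem cells' own markers, Lgr5 was at 5555 ± 2854 and 4167 ± 1488 and Olfm4 at 249440 ± 25870 and 233550 ± 7644, and neither passed the test.

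By limma, 67 genes were higher and 2 lower after IFNg among 16095 tested. All 67 were higher in each of the 3 pairs, 47 of them rose by at least 3 on the log2 scale, and their median log2 change was 3.70. The groups did not overlap for any of the 69 genes, and 13.2% of all tested genes had no overlap, where chance gives 10%. The lower genes were Bcl6 (log2 -3.63 ± 0.286 SE, adjusted p = 4.70e-04) and Gm38009, an unclassified transcript on chromosome 1 that went from 62.0 ± 5.26 to 5.16 ± 2.24 (adjusted p = 0.0450). Gm38009 was chosen after its values were seen, and it did not pass with the pairs as a block (0.0790), which left 1 lower gene, nor without untreated 1 (0.268), untreated 9 (0.299), IFNg 6 (0.0524), IFNg 2 (0.123) or IFNg 10 (0.137), with a range over the alternatives of 9.34e-07 to 0.772. At an unadjusted p under 0.05 there were 1362 higher and 122 lower genes. EdgeR on the recovered reads gave 60 higher and 2 lower, and DESeq2 gave 457 and 8.

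The number of higher genes depended on which libraries entered: it was 1331 in the 4 GFP3 libraries alone, 366 without untreated 5, 40 without IFNg 2, 44 without IFNg 10, 29 without libraries 1 and 2, 32 without 9 and 10, and 108 with the tag as a block. Of the 69 genes, 40 passed whichever library was left out, and 52 passed in limma, the blocked fit, edgeR and DESeq2 alike.

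**Figure D1:**
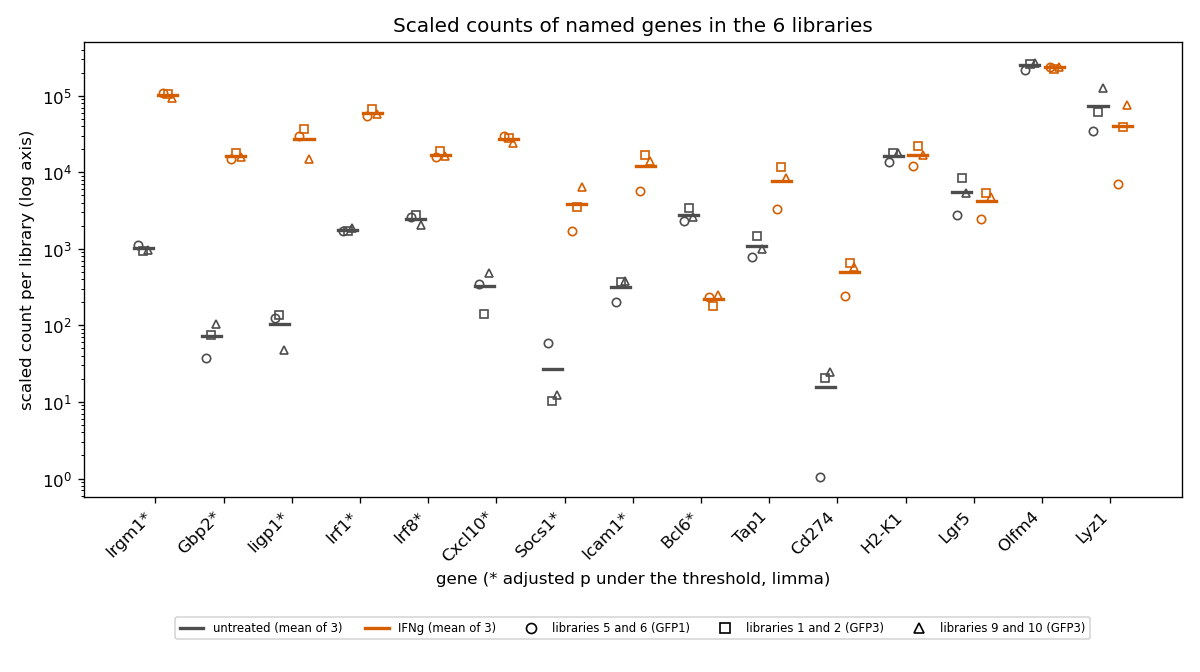
Scaled counts (log axis) of named genes in each of the 6 libraries, with grey symbols for untreated, orange for IFNg, a bar at each group mean and the symbol shape marking the pair. Irf1 lay near 1773.5 in untreated and 59642 in IFNg libraries, Bcl6 moved from 2766 to 222, and Lgr5 and Olfm4 overlapped between the groups.

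Guanylate-binding proteins and immunity-related GTPases, which coat and disrupt pathogen vacuoles, had the highest median log2 change of the 29 tested lists. Of 19 tested members 15 rose in limma, 17 when adjusted over the list alone, and 16 passed in DESeq2. The median log2 change was 5.99. Iigp1 (chromosome 18, 60376027 to 60392634, plus strand) rose 259-fold from 104 ± 49.5 to 26959 ± 11020 (log2 8.05 ± 0.478 SE, adjusted p = 1.00e-04). Gbp2 (chromosome 3, 142620602 to 142638008, plus strand) rose 223-fold from 72.6 ± 33.6 to 16217 ± 1633 (log2 7.90 ± 0.375 SE, adjusted p = 2.64e-05). Gbp7, on the same stretch of chromosome 3, rose 113-fold to 21404 ± 2300, and Irgm2 on chromosome 11 rose 110-fold to 10827 ± 2949 (166-fold without untreated 1). Gbp7 overlaps Gm43802 and Irgm2 overlaps Igtp on the same strand, so their values are uncertain. Tgtp1 and Gm12185, which overlap on the same strand of chromosome 11 and whose reads are therefore uncertain, rose 126-fold and 129-fold. The list's camera adjusted p was 1.45e-51, and 0.0502 with an estimated correlation.

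A pair of further genes near Iigp1 on chromosome 18 went from almost no reads to clear expression. BC023105, annotated as a processed pseudogene, had 1 read over the untreated libraries and 2085 over the IFNg libraries, a ratio of 1920 with an exact 95% interval of 344 to 75800 (log2 8.97, adjusted p = 7.47e-05). Gm4841 had 3 and 880 reads, a ratio of 270 with an interval of 92.1 to 1310 (adjusted p = 0.00100), and the ratio of mean scaled counts was 179 without untreated 5 and 608 without untreated 9. Both may share sequence with related GTPase genes, so their values are uncertain.

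Of 18 tested interferon regulatory transcription factors, 5 rose: Irf1 (log2 5.07 ± 0.230 SE, adjusted p = 2.33e-05), Batf2 (63.9-fold, to 3628 ± 783), Irf8 (6.89-fold, from 2470 ± 385 to 17023 ± 1490), Irf9 (4.48-fold, to 4188 ± 119) and Nlrc5, the transactivator of MHC class I genes (4.61-fold, from 190 ± 85.3 to 876 ± 61.4, adjusted p = 0.0446). Nlrc5 missed the threshold in edgeR (adjusted p = 0.0571) and without untreated 9 (0.172), IFNg 6 (0.0670), IFNg 2 (0.225) or IFNg 10 (0.203), with a range over the alternatives of 1.80e-06 to 0.632. The list's camera adjusted p was 7.59e-09, and 0.337 with an estimated correlation. Ciita, the class II transactivator in the same list, was at 531 ± 220 and 898 ± 531 and did not pass (adjusted p = 0.831).

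In the IFNg receptor and JAK-STAT list, 4 of 26 members rose (8 adjusted over the list alone). The feedback inhibitor Socs1, which blocks Jak kinases, rose 143-fold from 27.2 ± 27.5 to 3897 ± 2389 (log2 7.34 ± 0.691 SE, adjusted p = 0.00124). Without untreated 5 the ratio was 344-fold, and the log2 change was 4.83 in the GFP1 pair and 8.60 in the GFP3 pairs (interaction adjusted p = 0.0957, with 1 GFP1 library per group). Socs3 rose 12.2-fold from 1246 ± 553 to 15255 ± 2845. The interferon receptor chain Ifnar2 rose 4.48-fold (adjusted p = 0.0284, but 0.139 without untreated 1, 0.149 without untreated 9, 0.0504 without IFNg 6, 0.207 without IFNg 2 and 0.104 without IFNg 10). Stat2 rose 7.34-fold (11.1-fold without untreated 1, adjusted p = 0.0333, but 0.0691 with the block, 0.0554 in edgeR, 0.120 without untreated 9, 0.0670 without IFNg 6, 0.157 without IFNg 2 and 0.119 without IFNg 10, with a range of 5.90e-07 to 0.379). The receptor chains and kinases that IFNg itself uses did not pass in the main test. Jak2 had a log2 change of 1.16 (limma adjusted p = 0.280), but it passed in DESeq2 (0.00704) and adjusted over the list alone (0.0121). Log2 changes were 0.40 for Jak1 (limma adjusted p = 0.866) and -0.71 for Ifngr1 (0.561). Ifngr2 was at 1645 ± 1192 and 3249 ± 68.2 (0.403, but 0.0229 without untreated 5). The list's camera adjusted p was 2.17e-04, and 0.337 with an estimated correlation.

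Genes known from the type I interferon response also rose: 7 of 37 tested, 17 adjusted over the list alone, with 36 of 37 log2 changes above 0. Rtp4 rose 22.9-fold to 1917 ± 476, and Dtx3l, a ubiquitin ligase that works with Parp9, rose 8.03-fold to 7403 ± 1991. Parp14 rose 13.0-fold (adjusted p = 0.00377, but 0.0563 with the block, with a range of 7.61e-15 to 0.130). The list's camera adjusted p was 1.17e-22, and 0.0502 with an estimated correlation. In the chemokine and cytokine list 3 of 24 rose in limma (5 adjusted over the list alone, 5 with the block), and these 3 lie in neighbouring positions on chromosome 5. They were Cxcl10 and Cxcl9 (33.2-fold, to 747 ± 184), ligands of CXCR3, and Cxcl11 (61.4-fold, to 987 ± 336), which is annotated as a polymorphic pseudogene, so its transcript need not encode a ligand in these mice. That list's camera adjusted p was 0.00262, and 0.362 with an estimated correlation. Csf1, a macrophage growth factor, was at 56.8 ± 16.3 and 385 ± 208 (adjusted p = 0.0584). It passed with the block (0.0278), without untreated 5 (0.0464) and without IFNg 6 (0.0433), with a range of 2.69e-06 to 0.762. Cx3cl1, a membrane-bound chemokine chosen after its values were seen, was at 1871 ± 1142 and 19486 ± 12800 (adjusted p = 0.117). It passed with the block (5.09e-04), in DESeq2 (1.29e-05) and without IFNg 6 (0.0412), with a range of 1.29e-05 to 0.914.

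Immune checkpoint and tolerance ligands had 2 of 11 members that rose, 3 adjusted over the list alone. Icam1, an adhesion molecule for leukocytes, rose 38.6-fold from 315 ± 100 to 12153 ± 5804, and Ido1, which degrades tryptophan, rose 39.4-fold to 1286 ± 727. Cd274, the gene of PD-L1, was at 15.5 ± 12.7 and 492 ± 220 (log2 5.44 ± 0.912 SE). It fell just outside the threshold in limma (adjusted p = 0.0507) and inside it with the block (0.0170), in edgeR (0.0457), in DESeq2 (2.47e-09) and without untreated 5 (0.00634), with a range over the alternatives up to 0.424. The list's camera adjusted p was 1.18e-05, and 0.120 with an estimated correlation. Of 21 NF-kB targets 2 rose in limma, Cxcl10 and Icam1, which other lists also hold. Adjusted over the list alone 6 rose, and 6 passed in DESeq2. Nfkbiz had a log2 change of 1.56 (limma adjusted p = 0.185, but 0.0385 without untreated 5 and 0.00371 in DESeq2). Bcl3 had one of 2.54 (limma adjusted p = 0.271, but 7.21e-04 in DESeq2). The median of the NF-kB list was -0.0175, opposite in sign to its upward camera test, whose adjusted p was 0.00683, but 0.443 with an estimated correlation, 0.0758 without untreated 5 and 0.0584 without untreated 1.

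Few genes of antigen presentation passed at this time. In the MHC class I list 1 of 26 members rose, Nlrc5, and 2 did so adjusted over the list alone. Tap1, the peptide transporter, was at 1089 ± 367 and 7746 ± 4139 (log2 2.71 ± 0.463 SE) and missed the threshold (adjusted p = 0.0562). It passed with the block (0.00658), without untreated 5 (0.0484) and without IFNg 6 (0.00849), with a range over the alternatives of 8.32e-07 to 0.772. Psmb9, an immunoproteasome subunit whose gene overlaps Tap1 on the other strand of chromosome 17, had a log2 change of 0.81 (adjusted p = 0.454). H2-K1 was at 16362 ± 2556 and 16896 ± 4937, with a log2 change of 0.02 whose sign turned with TMM scaling. The class I list's camera adjusted p was 0.0341, but 0.443 with an estimated correlation, 0.107 without untreated 5, 0.0607 without untreated 9, 0.0550 without IFNg 6 and 0.355 without IFNg 2. In the MHC class II list 0 of 12 passed in limma and edgeR, 1 did in DESeq2, 1 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone, with a camera adjusted p of 0.840. Cd74 stood at 64191 ± 37900 and 46648 ± 26500.

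Of 35 caspase, death receptor and necroptosis genes 2 rose, Tnfrsf1a, the main TNF receptor, and Ripk1, the kinase that acts below it. Tnfrsf1a rose 8.65-fold from 1126 ± 244 to 9739 ± 3466 (adjusted p = 0.00353). Ripk1 rose 10.0-fold (from 648 ± 334 to 6497 ± 2473, adjusted p = 0.0124, but 0.120 with the block, 0.0817 without untreated 1, 0.0650 without IFNg 2 and 0.0610 without IFNg 10, with a range of 8.70e-10 to 0.330). Adjusted over the list alone 4 were higher, among them Mlkl, the necroptosis effector, and the nucleic acid sensor Zbp1. Mlkl was at 443 ± 84.7 and 1421 ± 273 (adjusted p over all genes 0.0562, 0.0278 with the block and 0.0300 without untreated 5, with a range of 1.59e-06 to 1). Zbp1 was at 117 ± 35.4 and 415 ± 37.4 (limma adjusted p over all genes 0.0656, but 0.0484 without untreated 5 and 6.54e-06 in DESeq2). The list's camera adjusted p was 0.0683. It passed with the block (0.0410), in edgeR (0.0396), without untreated 1 (0.0310), without untreated 9 (0.0423) and without IFNg 10 (0.0135). In camera with an estimated correlation, where no list passed, the list's adjusted p was 0.362, and 0.653 with the block as well. Without the block that correlation was 0.00911, below the preset 0.01. It therefore does not explain the rise of the unadjusted camera p from 0.0259 to 0.0873. In the BCL-2 family 0 of 20 members passed in limma, edgeR or DESeq2, or in limma over the list alone, with 2 at an unadjusted p under 0.05, and the camera adjusted p was 0.713. Bak1, a pore-forming killer of mitochondria, was at 103 ± 45.6 and 105 ± 55.5, and its log2 change of 0.01 turned negative with TMM scaling. Bik was at 164 ± 14.99 and 82.8 ± 18.8 (adjusted p = 0.372) and Mcl1 at 2566 ± 818 and 5205 ± 2532 (0.478).

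The lists of stem cell identity and proliferation did not pass. In the Lgr5 stem cell signature 0 of 32 genes passed in limma and edgeR and 2 in DESeq2, with 6 at an unadjusted p under 0.05 and 7 higher in the GFP3 libraries alone (camera adjusted p = 0.673). Among canonical Wnt targets 0 of 21 passed in limma and edgeR and 1 in DESeq2, with 3 at an unadjusted p under 0.05 (0.840). Ascl2, the transcription factor of crypt base stem cells, was at 358 ± 298 and 686 ± 158 (adjusted p = 0.507, but 0.0302 without untreated 5). Of 36 cell cycle genes 1 rose, Ung, a DNA repair glycosylase (4.05-fold, adjusted p = 0.0417, but 0.0621 with the block, 0.181 without untreated 1, 0.205 without untreated 9, 0.0524 without IFNg 6, 0.316 without IFNg 2 and 0.197 without IFNg 10, with a range of 7.65e-08 to 1), and the list's adjusted p was 0.840. Among p53 targets 0 of 21 passed in limma and edgeR and 1 in DESeq2, with 2 at an unadjusted p under 0.05 (0.840). Among Notch and secretory commitment genes 0 of 18 passed in limma and edgeR and 1 in DESeq2, with 3 at an unadjusted p under 0.05 (0.398, but 0.0340 without IFNg 6, and on all libraries adjusted p = 0.848 with an estimated correlation). On simulated data 52% of genes changed 4-fold and 4% of genes changed 2-fold were recovered, so changes near 2-fold in these lists would mostly have been missed.

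**Figure D2:**
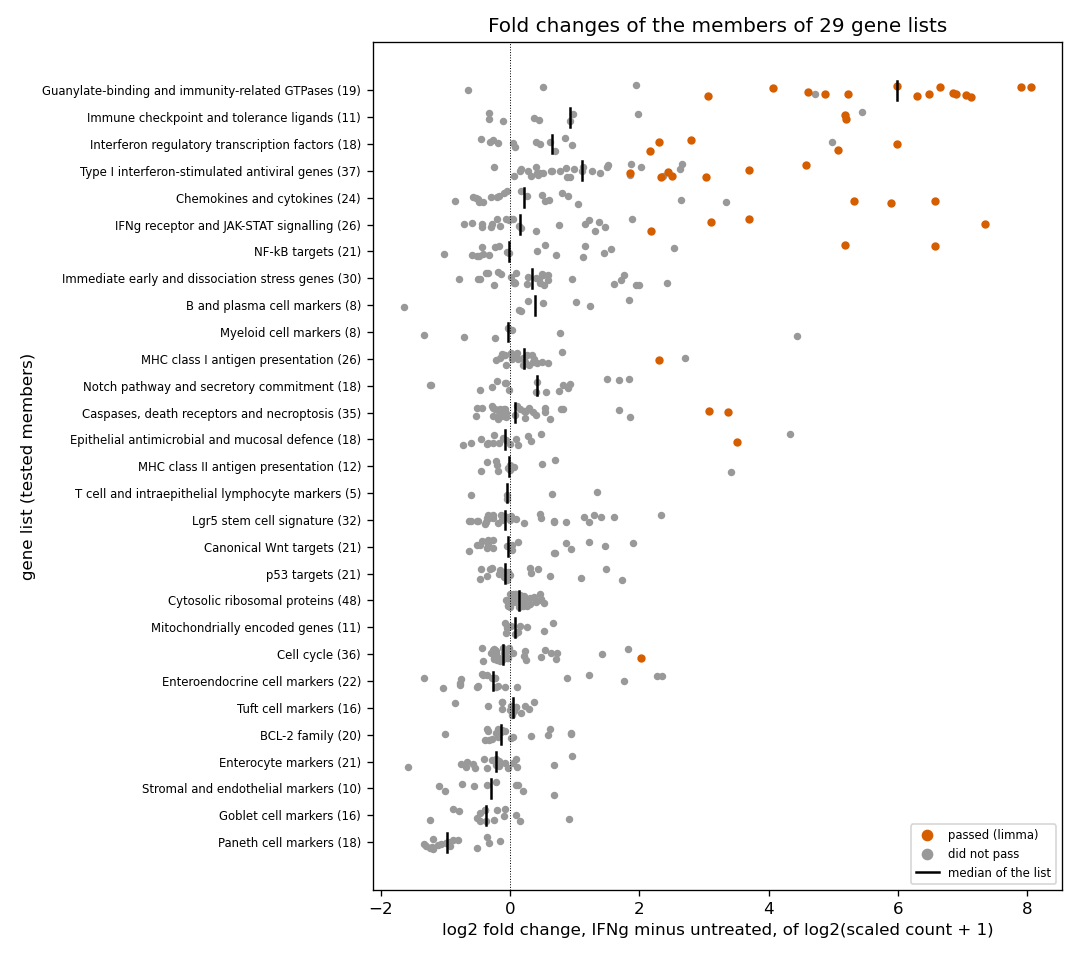
Log2 fold change (IFNg minus untreated) of each tested member of the 29 lists with a test, in orange where the gene passed in limma and in grey where it did not, with a black bar at the list median. The guanylate-binding and immunity-related GTPases had a median of 5.99, and all 18 Paneth cell markers lay below 0.

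Markers of other cell types and of RNA quality moved with the groups in part. All 18 Paneth cell markers, genes of the granulated neighbours of crypt stem cells, had log2 changes below 0 with a median of -0.98, and 0 passed in limma, edgeR or DESeq2 or had an unadjusted p under 0.05. The list was lower by camera (adjusted p = 5.86e-05, and 4.77e-07 with the block, but 0.632 with an estimated correlation, 0.0607 without untreated 9 and 0.153 without IFNg 6). Lyz1 was at 73929 ± 46370 and 40547 ± 34380, and Ang4 at 4595 ± 2108 and 2478 ± 1335. Immediate early and dissociation stress genes, which respond to cell handling, were higher as a list (0 of 30 passed in limma and edgeR and 5 in DESeq2, 6 at an unadjusted p under 0.05, adjusted p = 0.0176, but 0.443 with an estimated correlation, 0.192 without untreated 5 and 0.0590 without IFNg 10). In it, Egr1 had a log2 change of 1.95 (limma adjusted p = 0.211, but 0.0319 without IFNg 6 and 0.00108 in DESeq2). Jun had one of 1.61 (limma adjusted p = 0.294, but 0.0195 in DESeq2). Goblet cell markers (0 of 16 in all 3 tools, 1 at an unadjusted p under 0.05, adjusted p = 0.118) were lower with the block (0.0104), without untreated 1 (7.90e-05) and without IFNg 10 (8.98e-04). In camera with an estimated correlation, where no list passed, their adjusted p was 0.848, and 0.653 with the block as well. Enterocyte markers (0 of 21 in all 3 tools and at an unadjusted p under 0.05, 0.118) were lower with the block (0.0439) and without IFNg 2 (0.0379). Their adjusted p in camera with an estimated correlation was 0.443, and 0.550 with the block as well.

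Cytosolic ribosomal protein genes (0 of 48 in all 3 tools and at an unadjusted p under 0.05, adjusted p = 0.434) were higher with the block (0.0439), without untreated 5 (2.70e-04), without IFNg 2 (0.0379) and without IFNg 10 (0.00215), and lower without untreated 1 (3.22e-04) and without IFNg 6 (0.0340). Their estimated correlation was 0.966. In camera with an estimated correlation, where no list passed, their adjusted p was 0.970, and 0.967 with the block as well. Mitochondrially encoded genes did not pass (0 of 11 in all 3 tools and at an unadjusted p under 0.05, 0.840) but were lower without untreated 1 (0.00204), and on all libraries they had an adjusted p = 0.970 with an estimated correlation. Enteroendocrine markers (0 of 22 in limma and edgeR, 1 in DESeq2 and 1 at an unadjusted p under 0.05, 0.468) were lower without untreated 1 (0.00665) and without IFNg 10 (0.0135), and stromal and endothelial markers (0 of 10, 0.325) were lower without IFNg 10 (0.0373). On all libraries these lists had an adjusted p = 0.970 and an adjusted p = 0.848 with an estimated correlation. Markers of tuft cells (0 of 16, 0.996), T cells (0 of 5, 0.673), myeloid cells (0 of 8, 0.966) and B and plasma cells (0 of 8, 0.698) did not pass. In these 4 lists and the stromal list 0 genes passed in limma, edgeR or DESeq2, and at an unadjusted p under 0.05 there was 1 myeloid marker, Mpeg1, which also passed adjusted over the list alone. Mpeg1 was at 4.12 ± 7.14 and 51.2 ± 11.1 (adjusted p over all genes 0.244, but 0.0454 without untreated 9). The B and plasma cell markers had a mean log2 level of 2.22 in IFNg 2 and of -0.948 to -0.0448 in the other libraries. Igha was at 719 scaled counts in IFNg 2 and 0 to 4.12 in the others. The leukocyte gene Ptprc was at 27.0 ± 6.54 and 29.3 ± 16.04. Only 2 erythroid markers were tested, too few for a list test. In the antimicrobial defence list 1 of 18 rose, Apol9a (11.4-fold, to 192 ± 54.8, adjusted p = 0.0131, but 0.0754 without untreated 1 and 0.134 without IFNg 2), 2 did so adjusted over the list alone, and the list's adjusted p was 0.840.

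**Figure D3:**
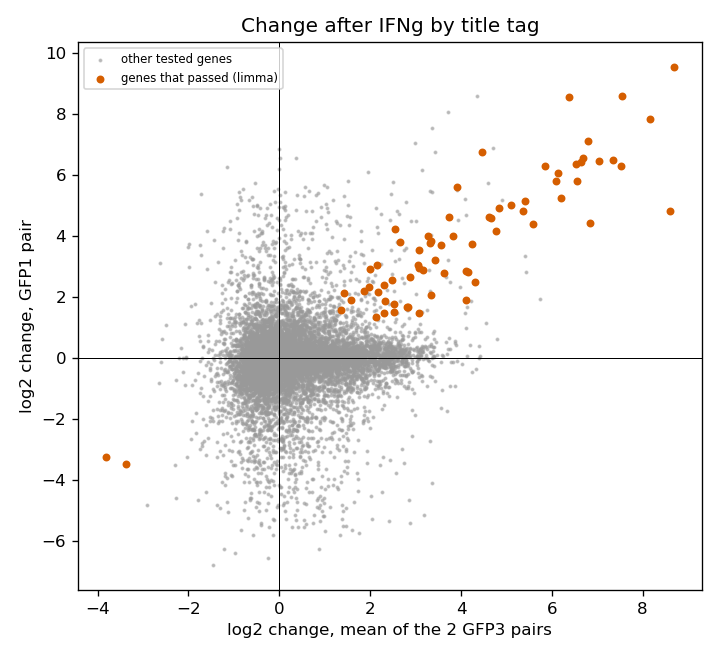
Log2 change of each tested gene in the GFP1 pair (IFNg 6 minus untreated 5, vertical axis) against the mean change in the GFP3 pairs (horizontal axis), with the 69 genes that passed in limma in orange. The orange genes lay on the same side of 0 on both axes, while an arm of grey genes was higher on the horizontal axis and near 0 on the vertical axis.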

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

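The fits corrected for transcript length and GC content, those without libraries 1 and 2 or 9 and 10, and the block with an estimated correlation were chosen after seeing the data. Of the 69 genes that passed, 27 passed under all alternatives that gave them a value, and none changed sign. The genes higher after IFNg numbered 457 with DESeq2, 108 with the tag as a block, 1331 in the GFP3 libraries alone, 29 without libraries 1 and 2 and 32 without 9 and 10, and 40 to 366 when 1 library was left out. Fewer samples entered the last 4 of these. The count of 366 came without untreated 5, and the cause was not tested beyond the test of the title tag given with the other observations. The genes lower numbered 1 with a pseudocount of 0.5, a minimum mean of 50, the replicate block, and without libraries 1 and 2 or 9 and 10, 8 with DESeq2, 12 in the GFP3 libraries, and 1 to 3 when 1 library was left out. Gm38009 was the gene lost in the block, and Bcl6 passed under all alternatives (log2 -3.81 to -3.33).

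The lists higher after IFNg fell from 9 to 0 with an estimated correlation, without or with the block, and to 6 with fry. They stood at 7 to 10 when 1 library was left out. A loss with an estimated correlation does not by itself show correlated genes, as given for the caspase, death receptor and necroptosis list. The lists lower went from 1 to 0 with an estimated correlation, without or with the block, and with fry, to 3 with the replicate block, 2 with the block and the length and GC correction, 3 without libraries 1 and 2, and 0 to 5 when 1 library was left out. The estimated correlation of the Paneth list was 0.729, and that of the GTPase list 0.326. The block, apart from the changes given in the report, changed no other call of a list. Among the genes that passed it also ended the calls of Gbp4, Serpina3f, Ero1l, Gm17334, Gm5431 and Ccnjl. The replicate block gave 74 higher genes, 58 of the 69 genes passed in it, and the median log2 change of all genes moved from -0.08 to -0.12 with TMM.

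Signs turned for genes and lists near 0. H2-K1 had log2 changes of -0.0292 with TMM, -0.0029 with edgeR, -0.0062 with the length and GC correction, without or with the replicate block, -0.12 without libraries 1 and 2, and -0.19 to 0.24 when 1 library was left out. Bak1 had -0.0371 with TMM, -0.0066 with edgeR, -0.0713 in the GFP3 libraries, -0.0874 with the length and GC correction, without or with the replicate block, -0.26 without libraries 1 and 2, and -0.39 to 0.33 when 1 library was left out. Ptprc had 0.0616 with edgeR, 0.16 with DESeq2, 0.68 in the GFP3 libraries and -0.39 to 0.52 when 1 library was left out. Igha had -2.00 without libraries 1 and 2 and -1.33 to 3.42 when 1 library was left out, the lowest without IFNg 2. With 1 library left out, Lgr5 ran from -0.77 to 0.0305, Cd74 from -0.88 to 0.0018 and H2-Ab1 from -0.80 to 0.0343, and the adjusted p of the mitochondrially encoded genes ran from 0.00204 to 0.560 and that of the cytosolic ribosomal proteins from 2.70e-04 to 0.232. The cause of these turns was not tested.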

Other observations

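The tests of depth, of sex and of the Paneth markers, and that of length and GC content on the excess of higher genes, were chosen only after the result was seen. Outside the lists, 29 further genes passed, and those named here were chosen after their values were seen. Pde4b, a cyclic AMP phosphodiesterase, rose from 322 ± 56.3 to 4715 ± 630 scaled counts (n = 3 per group), and Crem, a cyclic AMP-responsive transcription factor, from 958 ± 339 to 10582 ± 1222. The epithelial transcription factor Ovol2 went from 119 ± 69.9 to 1412 ± 156. Runx1, a transcription factor of blood lineages, rose from 394 ± 39.9 to 3211 ± 1505 (adjusted p = 0.00834, but 0.0592 without untreated 1 and 0.0538 without untreated 9). Tifa, an adaptor of innate signalling, rose 10.1-fold from 942 ± 341 to 9517 ± 2839, and Sectm1b, a secreted immune ligand, rose 10.4-fold from 2016 ± 525 to 21049 ± 8571.

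Genes higher after IFNg lay close together in the genome, as a test written before its result was seen showed: 29 of the 67 had another within 100 kb, against a median of 0 and a highest value of 10 in 10000 random sets of tested genes (permutation p = 1e-04, the smallest these sets can give). The clusters include the guanylate-binding proteins of chromosome 3, the GTPases of chromosomes 11 and 18 and Cxcl9, Cxcl10 and Cxcl11 on chromosome 5. Part of the count may come from genes that overlap and share reads, such as Gm17334 inside Irf1, 9330175E14Rik at the start of Nlrc5, and Irgm2 with Igtp.

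Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 67 higher genes and 2 lower, the highest of the others 0 and 0, so 1 split, the real one, reached each count. The other splits have no direction of their own. Their larger count was therefore set against the higher ones and their smaller count against the lower ones. For lists, 5 of the 10 splits gave as many as the 9 higher in this way, with a highest other of 11. As many as the 1 lower came from 8 splits, with a highest other of 8. Of the splits, 4 part all 3 pairs, and the other 3 of these gave at most 0 genes and 11 lists in a direction. The list counts alone therefore do not single out the treatment.

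Below the adjusted threshold, higher genes outnumbered lower ones: of genes not called, 1295 were higher and 120 lower at an unadjusted p under 0.05 in limma (91.5% higher). The counts were 1409 and 638 with the block (68.8%), and 1490 and 1044 with the block and a correction for transcript length and GC content (58.8%). The share thus fell through more lower genes, not fewer higher ones, so it does not decide whether length and GC content contributed. A difference held by the GFP3 libraries alone is a candidate explanation: 2387 uncalled genes were higher within them at an unadjusted p under 0.05, with a median log2 change of 1.61. Of these, 54.6% were higher in IFNg 6 than in untreated 5, against 50.8% of other uncalled genes, and their median change there was 0.04. Of 461 uncalled genes lower within the GFP3 libraries, 32.1% were higher in that pair, with a median change of -0.16, so lower changes were shared in part. All these shares come from 1 pair of libraries and give no measure of the spread between pairs. An interaction of treatment and tag in limma passed for 0 of 16095 genes (lowest adjusted p 0.0957, 2677 at an unadjusted p under 0.05, no other tool run), but with 1 GFP1 library per group it decides little, and the meaning of the tag is not given.

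The level of the lower Paneth markers ranged more widely within groups than the group means differed, though a range and a difference of means are unlike measures. Libraries 9 and 10 had the highest mean level of their groups (1.40 and 0.445, relative to the mean of all libraries), so part of the range may lie between pairs. The mean log2 level of the 18 markers ranged over 2.15 within the IFNg libraries and 1.58 within the untreated ones, against a difference between groups of -0.92. Paneth cell RNA that varies between libraries could give such a range, although a high Lgr5-GFP gate should remove most such cells. A difference shared by both libraries of a pair would cancel within it. With the pairs as a block, the list's camera adjusted p was 4.77e-07, and 0.550 with an estimated correlation. The median change was 0.0178 between libraries 1 and 2, -2.20 between 5 and 6 and -0.99 between 9 and 10. Each pair holds 1 library per group and the markers move together (estimated correlation 0.729), so a fall of similar size in every pair is not excluded, and an effect of IFNg on Paneth genes or cells stays open.

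Libraries 5 and 6, tagged GFP1, stood apart from the other 4 in the first principal component. Sequencing depth stays open, since IFNg 6 had 35959242 reads in genes (35.96 in units of 1e6), inside the range of the GFP3 libraries, but untreated 5 had 28508762, fewer than each of them. Sex of the animals is argued against, since untreated 9 and IFNg 10, which carry Y-linked reads as libraries 5 and 6 do, lay at 47.2 and 18.7, on the side of libraries 1 and 2. The tag explained 34.3% of the variance before correction for transcript length and GC content and 31.5% after it, so the correction took little of it. The highest other split of 2 against 4 libraries among 15, untreated 1 and 9, held 30.4% before and 31.6% after. A part of transcript length and GC content in the separation still cannot be told apart from other causes. Across genes, the deviation from a gene's mean over the 6 libraries correlated with its transcript length (Spearman) at -0.31 and -0.36 in libraries 5 and 6. In the others this correlation was 0.0043 to 0.30.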
